A study of Mus musculus with 6 samples.

How the data were processed

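Gene expression was measured in cells sorted from the olfactory epithelium of CD1 mice by flow cytometry with a fluorescent antibody against ICAM1 (CD54), a cell adhesion protein. Per the labels, the mice were between postnatal days 21 and 25. Each of 3 litters gave an ICAM1-positive and an ICAM1-negative sort, and each sort was hybridised to its own array, which makes 3 arrays per group and 6 in all. The litters were taken at postnatal days 21, 22 and 24, so age and litter cannot be separated. P-values of single probe sets rest on the spread between separate litters. The main p-values of gene lists compare the list's genes with other genes. Per the labels' protocols, RNA was extracted with TRIzol, amplified in 2 rounds, labelled and hybridised to an Affymetrix mouse genome array with 45101 probe sets. A control population of undissociated tissue was not used here.

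The authors deposited the values as linear intensities, with 1 decimal per value. The series text and the submitters' processing notes name GCRMA, whose output would be on a log2 scale with near-equal quantiles between arrays. The deposited intensities had different quantiles on each array, and their mean after trimming 2% from each end was 500 on every array, which is the form of signals scaled by Affymetrix MAS5-type software. They were therefore treated as scaled linear intensities. The program that made them, its background correction and its detection calls are not given in the sources used here. Median intensity per array lay between 87.9 and 102.8. Scanner files and scan dates were not used here, so a scan batch was not tested. The small number of arrays limits the precision.

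Groups were taken from the sample titles, source names and population labels. The free-text descriptions of the samples name the opposite population, and Icam1 was used to check this. Intensities were transformed to log2. The 64 control probe sets were left out, and a probe set was kept when its log2 intensity was above 4 (intensity above 16) on at least 3 of the 6 arrays, which left 38694. Gene names came from the platform table, in which 34958 probe sets had 1 gene, 932 had several and 9160 had no gene listed. The Entrez IDs of 34754 of the 34958 were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed updating; no coordinates were used. A gene was represented by the kept probe set of a single symbol with the highest mean over the 6 arrays, which gave 16399 genes. Of 2483 genes with 2 or more probe sets past the threshold, 2396 (96.5%) had all of these in the same direction.

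Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend), without a block for litter, as ICAM1-positive minus ICAM1-negative on the log2 scale. P-values were adjusted by Benjamini-Hochberg over the probe sets kept, with a threshold of 0.05. Errors beside a mean intensity are SD over 3 arrays and errors beside a log2 difference are the standard error of the fit. Low intensities carry no detection call, so a log2 difference against a near-background side has no exact fold. Where the dimmer sort lay below the array median on all of its arrays, its intensity was raised to that median and the fold is given as at least that size. This bound was chosen after the data were seen. It is an estimate without an error, so a difference is not shown where the call is lost with low intensities raised. Where only some arrays of the dimmer sort lay below the median, as for Krt14, the log2 difference is given but its size is uncertain as well.

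The 33 gene lists and the rule for named genes were fixed before the data were examined, as were all alternatives not described as added later. The lists cover horizontal basal cells, globose basal cells and neuronal precursors, immature and mature olfactory sensory neurons, sustentacular cells, microvillar and tuft cells, Bowman glands, ciliated cells, vascular endothelium, macrophages, neutrophils, lymphocytes, fibroblasts, pericytes, ensheathing glia, erythroid cells, hemidesmosomes, desmosomes, S phase, G2 and M phase, the Notch, Wnt, TGF-beta and EGF/FGF pathways, NF-kB, interferon, antigen presentation, immediate early genes, heat shock, axon guidance, xenobiotic metabolism, oxidative phosphorylation and stem cell regulators. Olfactory receptor genes, taken by symbol, made a further list. The lists hold 493 entries, of which 440 were measured. Each list was tested two-sided with camera in limma (preset inter-gene correlation 0.01), adjusted over the 34 lists, on the genes measured. Alternatives were camera with a correlation estimated for each list, and fry. Of the measured genes, another list also held 6 of the horizontal basal cell list, 6 of the sustentacular list, 4 each of the Notch, xenobiotic and stem cell lists, 3 of the hemidesmosome list, 2 of the EGF/FGF list and 1 each of the globose basal, immature neuron, Bowman, neutrophil, pericyte, glia, immediate early and axon lists, and 0 in the other 19 lists.

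Named genes were Icam1, the 8 largest changes in each direction among genes past the threshold with the same sign in every litter, up to 4 members of each list with the smallest p, and Trp63, Krt5, Krt14 and Omp. From each list the text gives the first of these in order of p. Genes named outside the rule, such as those that went against their list and Cyp2g1, were chosen after their values were seen. Of the 145 genes named by the rule, 134 passed the threshold, and all 134 had the same sign in each of the 3 litters. For 19 named genes the probe set is of a kind that can also bind related transcripts, among them Snai2, H2-Aa, H2-Ab1, Stx1a, Dsp, Fgfr1, Fgfr2, Gsto1, Cxcl1 and Ccdc39. Values of close paralogs such as Lyz1 and Lyz2, or Hspa1a and Hspa1b, are uncertain for the same reason.

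The replicate number marks the litter, per the labels, so it pairs the arrays. Deviations from the group means correlated at 0.127, 0.199 and 0.081 between the arrays of the same litter. A fit with litter as a block was an alternative. The others were no filter, a stricter filter (log2 above 6), a filter on the mean, a median shift, quantile normalization, an offset of 16, eBayes with trend and robust settings, a further threshold of 2-fold, counting genes, averaging a gene's probe sets, and leaving out each litter and each array. Raising low intensities to the array median, and a filter of log2 above 7, were added after seeing the data. The 3 prime minus 5 prime difference of the Gapdh and beta-actin controls was tested with a two-sided exact permutation test, whose smallest possible p for 3 against 3 is 0.1.

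The fits were tested on simulated data built from the real arrays' means and spread. With 200 of 38694 probe sets changed, 0.1% of 2-fold and 22.2% of 4-fold changes were called. With 12000 changed, 53.1% of 2-fold and 80.8% of 4-fold changes were called, and 3.9% of the calls were false. Simulated lists shifted 2-fold were called in 100% of cases, and 0.4 unshifted lists were called per run. Genes were simulated as independent of each other. The list result therefore does not cover correlated lists, such as G2 and M phase (estimated correlation 0.58) or xenobiotic metabolism (0.57).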

Results

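Expression was profiled in ICAM1-positive and ICAM1-negative cells of the olfactory epithelium of 3 mouse litters, with 1 array per sort and litter. ICAM1 is carried on the surface of horizontal basal cells, the quiescent stem cells at the base of this epithelium, and also by endothelial and immune cells. The comparison asks which transcripts distinguish the cells that carry it. Median intensity was 102.8, 96.1 and 91 on the ICAM1-negative arrays and 102, 87.9 and 100.1 on the ICAM1-positive arrays. Across probe sets, log2 intensities correlated at 0.934 to 0.944 between arrays of the same sort and at 0.762 to 0.794 between sorts. The first principal component held 69% of the variance and separated the sorts.

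Icam1, the antigen of the sort, was measured at 20.8 ± 10.9 in ICAM1-negative and 6974 ± 237 in ICAM1-positive cells (SD, n = 3), at least a 72.2-fold difference (log2 difference 8.51 ± 0.37, adjusted p = 0.000133). This follows the sample titles and not the free-text descriptions. It checks the labels and is not a finding between the groups.

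Genes of horizontal basal cells were far higher in the ICAM1-positive sort. The basal keratin gene Krt5 rose from 160.6 ± 63.1 to 24300 ± 1990 (SD, n = 3; log2 difference 7.32 ± 0.33, adjusted p = 0.000148), and Krt14 rose from 51.9 ± 38.7 to 16770 ± 571 (8.58 ± 0.49, or 7.41 with low intensities raised to the array median; adjusted p = 0.000192). Trp63, the transcription factor of basal cells of stratified epithelia, rose from 120.4 ± 103 to 21340 ± 582 (7.80 ± 0.57, or 7.32 with low intensities raised; adjusted p = 0.000335). Krt17, another keratin of this list, rose by at least 114-fold. Of the 15 horizontal basal cell genes, 13 rose and 2 fell, with a median log2 difference of 5.38. Those that fell were the transcription factor gene Bcl11b (-2.33) and the homeodomain-only gene Hopx (-2.32). The camera adjusted p was 8.29e-06, and adjusted p = 0.0923 with an estimated correlation.

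Genes of hemidesmosomes and the basement membrane, which anchor basal cells, followed the same direction. Of 14 measured genes 13 rose and 1 fell (median 4.04, camera adjusted p = 7.82e-07; adjusted p = 0.146 with an estimated correlation). Nid1, which encodes the basement membrane protein nidogen, fell with both sorts near background (adjusted p = 0.0288). The laminin gene Lama3 rose by 4.64 ± 0.19, the integrin gene Itga6 by 3.60 ± 0.16 and the collagen IV gene Col4a2 by 3.55 ± 0.17. Itgb4, the partner of Itga6 in hemidesmosomes, rose by at least 20.2-fold. Of 13 desmosome and junction genes 10 rose and 0 fell (median 2.48, camera adjusted p = 5.65e-05; adjusted p = 0.0923 with an estimated correlation). For higher and lower genes adjusted over the list alone, the counts were 10 and 1. The desmosomal cadherin gene Dsc3 rose by at least 72-fold, Dsc2 by 3.08 ± 0.18 on the log2 scale, and Perp, which encodes a desmosome-associated membrane protein, by 4.42 ± 0.27. Macrophage genes rose in the same arrays as these epithelial genes, 12 of 15 with a median of 3.48.

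**Figure D1:**
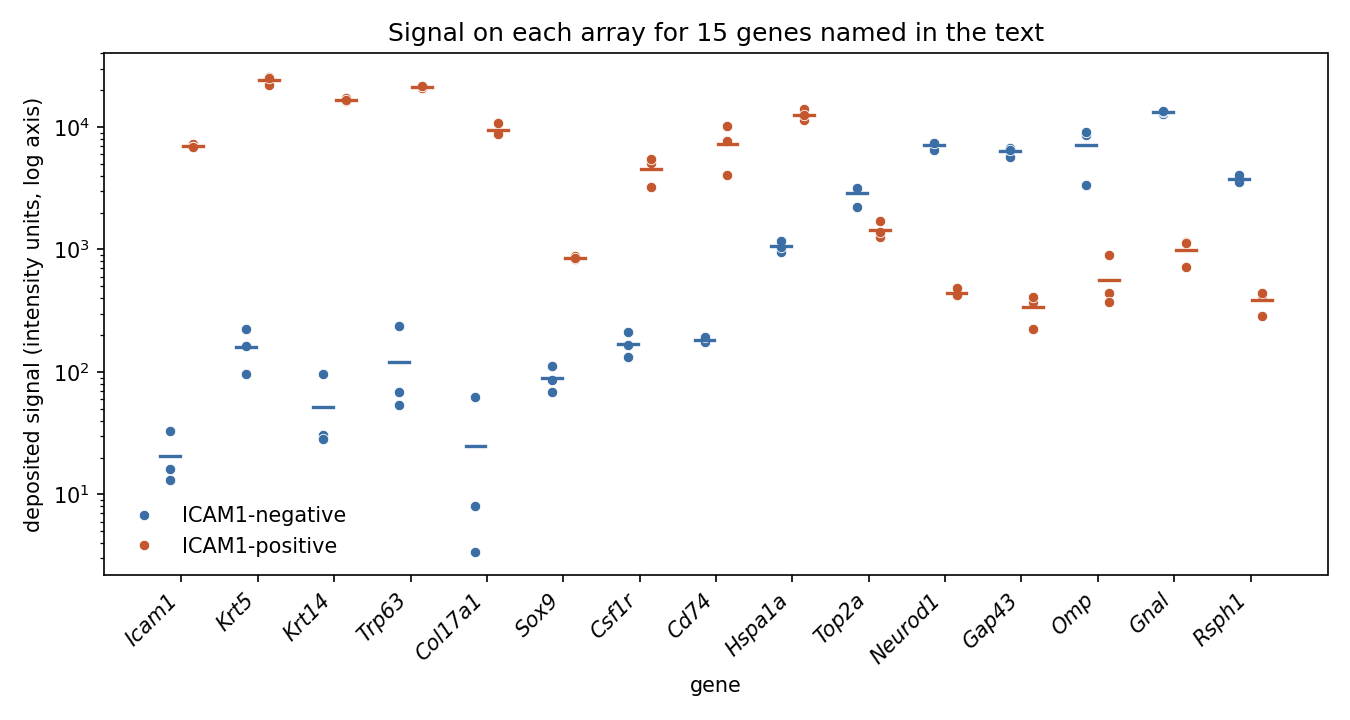
Deposited intensity on a log axis of 15 genes on each of the 6 arrays. Each point is an array, blue for ICAM1-negative and orange for ICAM1-positive, and each bar is the mean of 3 arrays; Krt5 has means of 160.6 and 24300, and Gnal has means of 13180 and 998.5.

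Over all probe sets, 6528 were higher and 6984 lower in ICAM1-positive cells, 34.9% of the 38694 tested, and 5366 and 5495 of them differed by 2-fold or more. Counted as genes, 3375 were higher, 3416 were lower and 9608 did not pass the threshold. Ranked by log2 difference, an order that near-background intensities on the dimmer side leave uncertain, the rises began with Col17a1, the transmembrane collagen of hemidesmosomes (9.61 ± 1.04, at least 97.1-fold), Krt15, a basal keratin (9.43 ± 0.54, at least 35.9-fold), Krt14, and Npl, a sialic acid lyase (8.56 ± 0.72, at least 38.1-fold). Next came Icam1, the chemokine gene Ccl20 (8.48 ± 0.37, at least 20.5-fold), Hcar2, a receptor for hydroxycarboxylic acids (8.43 ± 0.23, at least 29-fold), and Snai2, a zinc finger transcription factor gene (8.39 ± 0.46, at least 166-fold). The falls, ranked in the same way, began with Ccdc65, which encodes a protein of motile cilia (-6.35 ± 0.84), the synaptic adhesion gene Nlgn3 (-6.14 ± 0.30), Brinp2 (-5.98 ± 1.15), and the axonemal microtubule gene Togaram2 (-5.83 ± 0.91, or -4.16 with low intensities raised to the array median). They were followed by Sowaha (-5.59 ± 0.73), Podxl2 (-5.55 ± 0.44), the sulfotransferase gene Chst8 (-5.52 ± 1.02) and the non-coding Snhg11 (-5.44 ± 0.23). Adjusted p for these genes ran from 0.000124 for Hcar2 to 0.00996 for Brinp2. The falls are bounded at 4.99-fold for Ccdc65, 3.38-fold for Nlgn3, 4.67-fold for Brinp2 and 5.19-fold for Sowaha. Those of Podxl2, Chst8 and Snhg11 are bounded at 1.92-fold, 5.12-fold and 1.22-fold. Each bound is an estimated minimum without an error. Snhg11 lost its call when low intensities were raised to the array median (-0.29, adjusted p = 0.187), so its bound cannot be told from no difference. Leaving out a litter ended the call of Brinp2 (adjusted p = 0.102 without litter 1 and 0.0678 without litter 3), Togaram2 (0.0626 without litter 2) and Chst8 (0.0609 without litter 2). It lowered the counts of probe sets to 3764 higher and 3678 lower without litter 1, and to 3775 and 3915 without litter 3.

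Genes of olfactory sensory neurons were lower in ICAM1-positive cells. Gnal, the G protein of odorant transduction, fell from 13180 ± 360 to 998.5 ± 248 (SD, n = 3; log2 difference -3.76 ± 0.24, adjusted p = 0.000242), the phosphodiesterase gene Pde1c by 3.39 ± 0.17, and Ric8b, which encodes a chaperone of that G protein, by 3.14 ± 0.23. Omp, the olfactory marker protein gene, fell from 7070 ± 3220 to 568.2 ± 284 (-3.61 ± 0.52, adjusted p = 0.00329; 0.0518 without litter 1). Of 17 mature neuron genes 15 fell and 0 rose (median -3.61, camera adjusted p = 8.19e-07; adjusted p = 0.217 with an estimated correlation). Of 15 immature neuron genes 14 fell and 0 rose (median -3.57, camera adjusted p = 1.12e-06; adjusted p = 0.217 with an estimated correlation), among them the tubulin gene Tubb3 (-4.29 ± 0.23), the growth cone gene Gap43 (-4.28 ± 0.27) and the microtubule gene Dcx (-4.28 ± 0.28). Of 34 olfactory receptor genes 23 fell and 0 rose (median -2.45, camera adjusted p = 1.17e-06; adjusted p = 0.0923 with an estimated correlation). With low intensities raised to the array median, the receptor median was -0.67 and 18 were lower (adjusted p = 6.77e-05), so the size of this fall is uncertain.

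Genes of neuronal precursors and of axons and synapses fell as well. Neurod1, a transcription factor of neuronal precursors, fell from 7068 ± 493 to 444.8 ± 34.1 (SD, n = 3; log2 difference -3.99 ± 0.17, adjusted p = 0.000133), and the related Nhlh2 fell by 4.34 ± 0.31. Of 13 globose basal cell and precursor genes 11 fell and 1, the growth arrest gene Gadd45g, rose by 1.71 (median -2.09, camera adjusted p = 0.000143; adjusted p = 0.146 with an estimated correlation). Of 16 axon guidance and synapse genes 14 fell and 0 rose (median -3.08, camera adjusted p = 4.06e-06; adjusted p = 0.146 with an estimated correlation), and adjusted over the list alone the counts were 15 lower and 1 higher. Rims1 was at least 6.97-fold lower, and Stx1a, which like Rims1 acts in synaptic vesicle release, fell by 3.06 ± 0.21. The ephrin receptor gene Epha5 fell by 3.87 ± 0.31.

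Among the other epithelial cell types, genes of ciliated cells fell and detoxification genes rose. Of 12 ciliated cell genes 10 fell and 0 rose (median -3.22, camera adjusted p = 3.33e-05; adjusted p = 0.146 with an estimated correlation), including the radial spoke gene Rsph1 (-3.33 ± 0.22) and the tektin gene Tekt1 (-3.12 ± 0.22). Of 13 xenobiotic metabolism genes 10 rose and 0 fell (median 3.16, camera adjusted p = 5.56e-05; adjusted p = 0.274 with an estimated correlation). The aldehyde dehydrogenase gene Aldh3a1 rose from 95.7 ± 33.2 to 10220 ± 1040 (SD, n = 3; 6.79 ± 0.28, adjusted p = 0.000133), and the monooxygenase gene Fmo2 rose by 4.74 ± 0.25. Of 14 sustentacular cell genes 7 rose and 0 fell (median 0.84, camera adjusted p = 0.0296; adjusted p = 0.509 with an estimated correlation). With litter as a paired block this list missed the threshold (0.0765), as it did without litter 2 (0.106), without ICAM1-positive array 2 (0.0717) and without ICAM1-positive array 3 (0.0647). Of its genes, Fmo2 and the glutathione transferase gene Gsto1 rose by 4.74 ± 0.25 and 5.49 ± 0.30. Cyp2g1, a cytochrome P450 of sustentacular cells, stood at 11040 ± 3760 in ICAM1-negative and 9501 ± 4660 in ICAM1-positive cells and did not pass (-0.29, adjusted p = 0.661). Of 11 Bowman gland genes 5 rose and 0 fell. The list did not pass by camera (median 0.34, adjusted p = 0.113) but was higher by fry (adjusted p = 9.95e-05). With litter as a paired block 1, Obp2a, was lower (adjusted p = 0.0473). Sox9, a transcription factor of gland and duct cells, rose by 3.29 ± 0.22 and the water channel gene Aqp5 by 4.22 ± 0.35, and the others were Krt7, Lyz2 and Bpifa1. Lyz2 cannot be assigned to gland cells here, since its close paralog Lyz1 is on the macrophage list and macrophage genes rose as well. Of 12 microvillar and tuft cell genes 1, the keratin gene Krt18, rose (2.23 ± 0.16) and 6 fell. With litter as a paired block 2 were lower, as Ascl3 (adjusted p = 0.082), Hepacam2 (0.0896), Trpm5 (0.0514) and Sh2d6 (0.0858) lost their calls. The actin-bundling gene Avil was at least 3.94-fold lower and the cytokine gene Il25 at least 4.55-fold lower. The list did not pass (median -1.21, camera adjusted p = 0.22); without litter 3 it did (adjusted p = 0.0342). Macrophage genes, 12 of 15, rose in the same arrays as the detoxification, sustentacular and gland genes. Mature neuron genes (15 of 17, median -3.61) and immature neuron genes (14 of 15, median -3.57) fell in the same arrays as the ciliated genes.

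Genes of monocytes and macrophages rose in the ICAM1-positive sort. Ctss, a lysosomal protease gene of these cells, rose from 248.5 ± 28.2 to 6254 ± 908 (SD, n = 3; log2 difference 4.65 ± 0.20, adjusted p = 0.000133), Csf1r, their growth factor receptor gene, rose by 4.75 ± 0.29, and the endotoxin co-receptor gene Cd14 by 3.32 ± 0.19. Of 15 genes 12 rose and 0 fell, or 14 and 0 adjusted over the list alone (median 3.48, camera adjusted p = 7.82e-07; adjusted p = 0.146 with an estimated correlation). Antigen presentation genes rose in the same arrays, 12 of 13 with 0 lower, or 13 adjusted over the list alone (median 2.78, camera adjusted p = 8.19e-07; adjusted p = 0.146 with an estimated correlation). The class II gene H2-Eb1 rose by at least 42.4-fold, H2-Aa by 5.83 ± 0.29 on the log2 scale, and the invariant chain gene Cd74 from 181.3 ± 10.2 to 7307 ± 3140.

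Among other blood, vascular and stromal cell types, the erythroid list was lower by camera and the other lists did not pass by camera. Of 12 neutrophil genes 1, the lipocalin gene Lcn2, rose (3.06 ± 0.39) and 2, Cxcr2 and Ngp, fell, and the list did not pass (median -0.64, camera adjusted p = 0.327). Ngp, a granule protein gene, fell by 1.45 ± 0.33 and lost its call without litter 1 (adjusted p = 0.157), litter 2 (0.0672), ICAM1-negative array 1 (0.0635), ICAM1-positive array 1 (0.0636) or ICAM1-positive array 3 (0.0604). The chemokine receptor gene Cxcr2 was near background in both sorts, at 35.7 ± 8.69 and 7.57 ± 2.01, and lost its call with low intensities raised to the array median (adjusted p = 0.996). With litter as a paired block 5 neutrophil genes were lower. Of 6 lymphocyte genes 1 fell, the B cell gene Ms4a1. The list did not pass by camera (median -0.55, adjusted p = 0.221) but was lower by fry (adjusted p = 0.00686). Ms4a1 was at least 1.41-fold lower and lost its call without litter 2 (adjusted p = 0.137), litter 3 (0.0657) or a single array, ICAM1-negative 1 or 2 or ICAM1-positive 2 or 3 (0.0596 to 0.0659), and with low intensities raised to the array median (0.288). Of 6 erythroid genes 4 fell, or 5 adjusted over the list alone (median -1.95, camera adjusted p = 0.0165; adjusted p = 0.217 with an estimated correlation). The list missed the threshold with low intensities raised to the array median (0.0988). Genes of mature neurons (median -3.61) and immature neurons (median -3.57) fell in the same arrays. The carbonic anhydrase gene Car2 fell by 3.69 ± 0.42, and the others, Slc4a1, Klf1 and Alas2, lost their calls without litter 3 (adjusted p = 0.0553 to 0.107). Slc4a1 and Klf1 also lost them without litter 1 (0.0548 and 0.0993), Klf1 with low intensities raised to the array median (0.482), and Alas2 without litter 2 (0.0709), ICAM1-negative array 3 (0.0557) or ICAM1-positive array 1 (0.0549). Of 13 endothelial genes 1 rose, the receptor component gene Ramp2 by at least 1.99-fold (median 0.24, camera adjusted p = 0.736). Of 14 fibroblast genes 2 rose and 2 fell, with a median of -0.18 and a mean of -0.13 against a test direction upward (camera adjusted p = 0.92). The matrix genes Fbln1 and Dcn rose by 1.99 ± 0.26 and 1.93 ± 0.28, the second not with its probe sets averaged (adjusted p = 0.0629). The collagen VI gene Col6a1 was at least 2.73-fold lower, and Col6a2 at least 1.97-fold lower but not without litter 1 (0.116) or litter 3 (0.0875). Of 11 pericyte and smooth muscle genes 1, the actin-binding Tagln, rose by at least 1.35-fold (adjusted p = 0.00988; 0.0962 without litter 1 and 0.0801 without litter 3), with a list median of -0.19 and camera adjusted p = 0.92. With litter as a paired block 2 were higher and 1 lower, as Cspg4 (adjusted p = 0.0263) passed upward and Abcc9 (0.0146) downward. Of 11 ensheathing glia genes 3 rose and 1 fell (median 0.16, camera adjusted p = 0.49). The BMP and Wnt antagonist Sostdc1 rose by at least 23.6-fold and the neurotrophin receptor gene Ngfr by at least 4.5-fold, the second not without litter 3 (adjusted p = 0.0649). Erbb3 rose by 0.95 ± 0.21, but not without litters 1 (0.111), 2 (0.0713) or 3 (0.0678) or ICAM1-positive array 3 (0.0559). The myelin gene Mbp fell by 1.45 ± 0.31, but not without litters 1 (0.107) or 3 (0.0863) or ICAM1-negative arrays 1 (0.0543) or 3 (0.0514).

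Genes of several signalling pathways were higher in ICAM1-positive cells. Hes1, a target of Notch signalling, rose from 344.6 ± 20.9 to 8391 ± 698 (SD, n = 3; log2 difference 4.60 ± 0.17, adjusted p = 0.000124), and the ligand gene Dll1 by 4.85 ± 0.25. Of 14 Notch genes 9 rose and 1, the ligand gene Dll3, fell (median 2.04, camera adjusted p = 0.00343; adjusted p = 0.166 with an estimated correlation). Of 15 Wnt genes 13 rose and 1 fell, the target gene Axin2 (-0.99) (median 2.95, camera adjusted p = 5.07e-06; adjusted p = 0.0923 with an estimated correlation). Its leading members were the antagonist Sfrp1 (4.95 ± 0.20), the transcription factor Tcf7l2 (3.59 ± 0.16) and Dkk3 (5.35 ± 0.27). Of 15 TGF-beta and BMP genes 11 rose and 1 fell, or 12 and 1 adjusted over the list alone (median 2.09, camera adjusted p = 4.7e-05; adjusted p = 0.217 with an estimated correlation). The inhibitor Smad7 rose by 2.99 ± 0.18 and the transducer Smad3 by 2.85 ± 0.18, and the gene that fell was the receptor Tgfbr1 (-0.76). Of 16 EGF and FGF genes 12 rose and 1 fell, the transcription factor Etv4, at least 2.16-fold (median 3.29, camera adjusted p = 0.000116; adjusted p = 0.0923 with an estimated correlation). The receptor gene Fgfr2 rose by 4.62 ± 0.18 and the phosphatase gene Dusp6 by 3.23 ± 0.16. Of 15 stem cell regulators 10 rose and 3 fell, or 10 and 4 adjusted over the list alone (median 1.96, camera adjusted p = 0.00768; adjusted p = 0.166 with an estimated correlation). Those that fell were Ezh2 (-1.72) and Bmi1 (-0.80) of the Polycomb complexes and the cell cycle inhibitor Cdkn1c (-1.59). The transcription factor gene Myc rose by at least 5.7-fold and Klf4 by 3.44 ± 0.23. The macrophage genes, 12 of 15, rose in the same arrays as each of these pathways.

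Stress and inflammatory genes were higher in ICAM1-positive cells. The early response gene Atf3 rose from 2278 ± 268 to 23010 ± 2360 (SD, n = 3; log2 difference 3.34 ± 0.18, adjusted p = 0.000177), Ier3 rose by 4.54 ± 0.19, and Zfp36, an mRNA decay factor, by 4.23 ± 0.21. Of 15 immediate early genes 14 rose and 0 fell (median 3.02, camera adjusted p = 1.2e-07; adjusted p = 0.146 with an estimated correlation), and Fos, at 0.36, did not pass. Of 11 heat shock genes 5 rose and 1, the co-chaperone Dnaja1, fell (median 0.99, camera adjusted p = 0.0182; adjusted p = 0.146 with an estimated correlation). The chaperone genes Hspa1a and Hspb1 rose by 3.58 ± 0.18 and 3.85 ± 0.24, and the others were Dnajb1, Bag3 and Hspa1b. Of 14 NF-kB and cytokine genes 12 rose and 0 fell, or 13 adjusted over the list alone (median 2.77, camera adjusted p = 1.17e-06; adjusted p = 0.146 with an estimated correlation). The cytokine gene Il6 rose from 88.6 ± 26.5 to 5482 ± 1040 (5.97 ± 0.28), and the chemokine gene Cxcl1 by 3.88 ± 0.24. Of 11 interferon response genes 7 rose and 3 fell, or 8 and 3 adjusted over the list alone. The transcription factor gene Irf1 rose by 4.55 ± 0.20, and the interferon-induced genes Ifit1, Ifit2 and Rsad2 were those that fell. This list was close to the threshold (median 1.80, camera adjusted p = 0.0498; adjusted p = 0.183 with an estimated correlation) and missed it with litter as a paired block (0.0631), under 3 other filters (0.0527 to 0.16) and with low intensities raised to the array median (0.0988). It also missed it without litter 1 (0.0553), ICAM1-negative array 1 (0.065), ICAM1-negative array 3 (0.0587) or ICAM1-positive array 2 (0.0625). Macrophage genes, 12 of 15 with a median of 3.48, rose in the same arrays as each of these groups.

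The G2 and M phase list was lower in ICAM1-positive cells by camera, and the S phase and respiration lists did not pass by camera. Globose basal cell and precursor genes, 11 of 13 with a median of -2.09, fell in the same arrays. Of 17 genes of G2 and M phase 6 fell and 0 rose, or 7 lower adjusted over the list alone and 4 with litter as a paired block (median -0.73, camera adjusted p = 0.00465; adjusted p = 0.481 with an estimated correlation). Ube2c, a ubiquitin-conjugating enzyme gene of mitosis, fell from 704.6 ± 166 to 194.7 ± 37.5 (SD, n = 3; log2 difference -1.85 ± 0.26, adjusted p = 0.00294). Other named genes of this list were less stable. Top2a and Ccna2 lost their calls whichever litter was left out (adjusted p = 0.0575 to 0.18), and Aurka without litter 1 (0.0563). Ccna2 also lost its call with litter as a paired block (0.0604), and Top2a with its probe sets averaged (0.0566). Of 16 S phase genes 1 rose and 2 fell, and 0 passed adjusted over the list alone. The median was 0.03 and the mean 0.01 against a test direction downward (camera adjusted p = 0.961). Gins2 rose and Mcm7 and Cdc6 fell, and each lost its call whichever of the 3 litters was left out (adjusted p = 0.0555 to 0.195). Of 15 oxidative phosphorylation genes 4 fell and 0 rose, or 3 adjusted over the list alone (median -0.47, camera adjusted p = 0.0754). By camera the list passed after quantile normalization (0.0192), without ICAM1-negative array 1 (0.041) and without ICAM1-positive array 2 (0.0423). It was also lower by fry (adjusted p = 0.0155). The respiratory chain and ATP synthase genes Ndufa4, Ndufb8, Cox5a and Atp5o fell, but not without litter 1 (adjusted p = 0.0704 to 0.163) or litter 3 (0.0843 to 0.266), and Ndufb8 and Atp5o not without litter 2 (0.0616 and 0.0653). Ndufb8 had a probe set called in the opposite direction and stood at 0.29 with its probe sets averaged (adjusted p = 0.225). A median shift ended the calls of Cox5a (0.0522) and Atp5o (0.0894), and Atp5o also lost its call with no filter (0.0623) and with its probe sets averaged (0.0945).

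**Figure D2:**
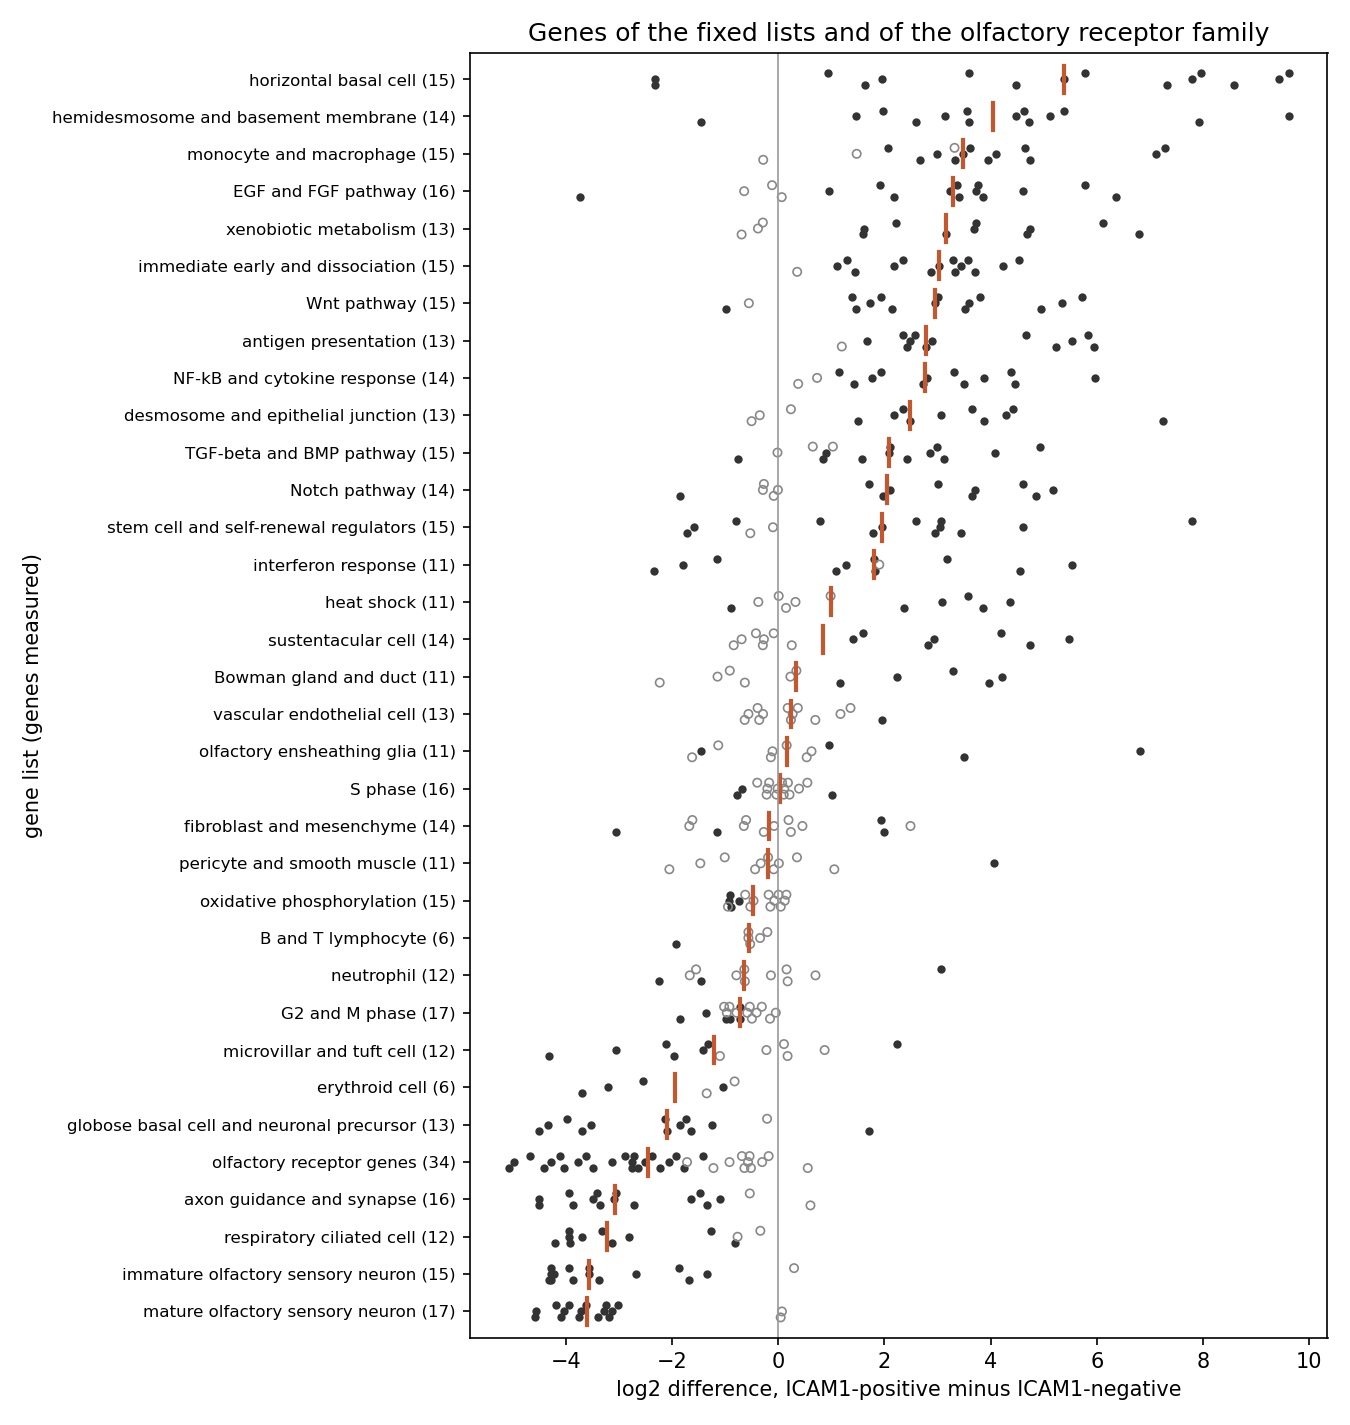
Log2 difference, ICAM1-positive minus ICAM1-negative, of the measured genes of 33 fixed lists and of the olfactory receptor genes, ordered by the list's median (orange bar). Filled points passed the threshold and open points did not; medians run from -3.61 for mature olfactory sensory neurons to 5.38 for horizontal basal cells.

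In all, 16 of the 33 fixed lists were higher and 7 were lower by camera. With an estimated correlation 0 passed, with a smallest adjusted p of 0.0923, and 8 passed unadjusted. The alternative fry called 17 higher and 9 lower, adding the Bowman gland list upward and the lymphocyte and oxidative phosphorylation lists downward. In 22 of the 34 lists, the counts adjusted over the list alone equalled those over all genes tested. With litter as a paired block, a list's counts of higher and of lower genes each changed by at most 2, except those of lower microvillar and neutrophil genes given above.

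RNA quality was compared through the control probe sets for Gapdh and beta-actin. The Gapdh 3 prime minus 5 prime log2 difference was 1.13 ± 0.09 in ICAM1-negative and 1.55 ± 0.07 in ICAM1-positive cells (SD, n = 3; difference 0.42, two-sided exact permutation p = 0.1, the smallest this design allows). For beta-actin it was 1.53 ± 0.17 and 1.43 ± 0.24 (difference -0.09, exact permutation p = 0.5).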

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

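The tests of neutrophil genes, of end bias, of sustentacular cells and of neuron loss were chosen only after the result was seen.

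Of 10 control probe sets outside the comparison, 4 separated the sorts and 6 did not. The 6 were those for 18S RNA and the 5 prime (-0.12) and middle (0.53 and 2.09) pyruvate carboxylase controls. The middle part at 2.09 read 18.1 ± 9.49 in ICAM1-negative and 86.1 ± 54.3 in ICAM1-positive cells, with overlapping arrays. The transferrin receptor controls read 41.4 ± 19.4, 9.93 ± 5.17 and 10.1 ± 8.19 in ICAM1-negative and 164 ± 19.4, 36.2 ± 7.99 and 41.1 ± 11.2 in ICAM1-positive cells for their 3 prime, 5 prime and middle parts (SD, n = 3), log2 differences of 2.13, 2.01 and 2.39. The ICAM1-negative side lay near background in all of these parts, so the differences have no exact size. The 3 prime pyruvate carboxylase control read 233 ± 27.7 and 652 ± 91.7, a log2 difference of 1.48. In each of the 4, every ICAM1-positive array lay above every ICAM1-negative array (exact permutation p = 0.1, the smallest possible), which chance gives in 10% of such comparisons counted in either direction.

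Macrophage genes rose with the ICAM1-positive sort. If macrophages had been collected with it, other macrophage genes would rise: in a further list written before its values were seen, 16 of 19 measured genes were higher (84.2%, median 2.47) against 20.6% of all genes, and 13 of the 19 lay below the array median on every ICAM1-negative array. No gate against blood cells is given in the sources used here. Of 5 neutrophil genes with intensities over 500, 4, all but Lcn2, had 95% upper limits of -0.63 to 0.04, below the macrophage median of 3.48. For these 4 genes this argues against a rise as large as that of the macrophage genes. It does not exclude neutrophils, since which cells expressed the genes was not tested and Ltf is also on the Bowman gland list. Most lymphocyte genes were too dim to decide, and other leukocytes were not tested. Macrophages or other leukocytes that carry ICAM1 remain a candidate source of these transcripts. Expression of the same genes by epithelial cells remains open and was not tested.

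Immediate early genes (14 of 15) rose with the same sort, as did 5 of 11 heat shock genes, while 1 heat shock gene fell. A stronger reaction to dissociation and sorting predicts a rise of other stress genes, and 15 of 18 genes of a further stress list, written before its values were seen, were higher (83.3%, median 2.42) and 1 was lower. This does not separate a reaction to handling from a higher level in the tissue, because no undissociated sample was analysed. The further list shares no gene with the heat shock list, so it does not bear on those genes. An end bias of the amplified RNA could not be decided, since the 3 prime minus 5 prime difference rose for Gapdh (0.39 to 0.43 by litter) and fell for beta-actin in every litter (-0.19, -0.01 and -0.08), but the beta-actin mean of -0.093 had a 95% interval of -0.31 to 0.12. A higher level in these cells in the tissue may equally hold and was not tested.

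Detoxification genes rose with the ICAM1-positive sort. More sustentacular cells, which are rich in such enzymes, would raise sustentacular genes together, and 7 of 14 rose. Of 9 over 500 in a sort that could rise by the detoxification median of 3.16 without passing the highest intensity of the arrays, 4 (Sult1c1, Cyp1a2, Aldh1a7 and Muc2) had 95% upper limits of 0.49 to 1.08, which argues against more of these cells as the whole cause, while a part in the rise stays open. Fewer neurons would raise all other cell types alike. Genes of the ciliated list fell (median -3.22, 10 of 12 lower), in the same arrays as the neuron genes. They cannot decide this, since which cells expressed them was not tested. The microvillar median of -1.21 adds little, with 2 of its 6 falls kept with litter as a paired block. Expression of the genes by basal or gland duct cells among the ICAM1-positive cells may account for the rise and was not tested. The Bowman gland list (5 of 11 higher, median 0.34) did not pass by camera (adjusted p = 0.113) but was higher by fry (adjusted p = 9.95e-05).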

How the results depend on the processing

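The floor at the array median and the filter of log2 above 7 were chosen only after the data were seen. Icam1 stayed past the threshold under every alternative, at 6.17 (low intensities raised to the array median) to 8.92 on the log2 scale. With a replicate block for litter, 6899 probe sets were higher and 7476 lower, and 12522 of the 13512 calls remained. In this fit Icam1 had adjusted p = 0.00406, and lists numbered 14 and 7. The block ended the calls of the interferon and sustentacular lists and of Ccna2 and Ascl3. It made those of Mmp8, Cspg4 and Abcc9, and changed no other list and no other gene named by the rule. Counted as genes, 3375 were higher and 3416 lower, which reflects fewer features. Leaving out a litter or an array, which reduces the samples, gave 3764 to 5854 higher and 3678 to 6013 lower; without litter 1, 7088 of the 13512 calls remained, and without litter 3, 7319. With an estimated correlation 0 lists were higher, 0 were lower, and the olfactory receptor median of -2.45 had adjusted p = 0.0923; the cause was not tested. The Gapdh 3 prime minus middle difference was 0.087 in place of 0.418. Ndufb8 reversed when its probe sets, which were called in opposite directions, were averaged (0.29, adjusted p = 0.225). Of 133 named genes past the threshold besides Icam1, 12 apart from this reversal lost the call under some alternative with all 6 arrays and 26 when arrays were left out. Scaling moved the median of all probe sets, -0.06, by under 0.1. With low intensities raised to the array median, the median of the horizontal basal cell list was 4.34 in place of 5.38, of macrophages 2.38 in place of 3.48, of olfactory receptors -0.67 in place of -2.45 with 18 lower, of the interferon list 0.88 in place of 1.80, of erythroid genes -0.96 in place of -1.95, of NF-kB genes 1.42 in place of 2.77 and of mature neurons -3.61 as before.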

Other observations

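The 31 gene families here were taken by symbol after the data had been seen, and so were the tests on them; the test of other splits was fixed before its result was seen.

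Many families divided as the fixed lists did, in part through the same genes. The fixed lists hold 3 of the 8 laminins, 4 of the 25 integrins, 5 of the 19 glutathione S-transferases, 4 of the 29 chemokines and 3 of the 12 axonemal dyneins, and 0 of the other families named here. Of 8 laminin genes 7 were higher in ICAM1-positive cells and 0 lower (median log2 difference 4.09, camera adjusted p = 0.000774; adjusted p = 0.142 with an estimated correlation), among them Lama1, at least 5.58-fold, and Lamb3 of the hemidesmosome list, from 54.5 ± 32.5 to 11960 ± 854 (SD, n = 3). Of 10 annexin genes 8 were higher (0.142 with an estimated correlation), among them Anxa8, from 85.7 ± 27.6 to 5705 ± 905 (SD, n = 3), and of 25 integrin genes 11 were higher and 1, Itgb8, lower (0.201). Of 19 glutathione S-transferase genes 14 were higher and 1 lower (median 2.21; 0.142), and of 10 carboxylesterase genes 6 were higher (0.24), among them Ces2b, at least 47.3-fold. Of 29 chemokine genes 15 were higher and 2 lower (0.142), among them Ccl20 (at least 20.5-fold) and Ccl22 (at least 7.06-fold). Of 45 cytosolic ribosomal protein genes 23 were higher and 0 lower, with a small median of 0.65 (camera adjusted p = 3.39e-06; adjusted p = 0.213 with an estimated correlation). Macrophage genes, 12 of 15 with a median of 3.48, rose in the same arrays as each of these families.

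Among families that were lower, 12 of 14 intraflagellar transport genes fell and 0 rose (median -1.39, camera adjusted p = 8.83e-05; adjusted p = 0.142 with an estimated correlation), as did 7 of 8 Bardet-Biedl genes, which serve cilium traffic (median -1.88, camera adjusted p = 0.00107; adjusted p = 0.142 with an estimated correlation). Of 12 axonemal dynein genes 6 fell and 0 rose (0.142). Of 25 voltage-gated potassium channel genes 12 fell and 0 rose (0.142), among them Kcnq3 (at least 1.98-fold), and of 10 sodium channel genes 6 fell and 1, Scn7a, rose (0.207), at intensities near background (13.0 ± 1.94 and 34.0 ± 10.6). Mature neuron genes (15 of 17, median -3.61) and immature neuron genes (14 of 15, median -3.57) fell in the same arrays as these families. With an estimated correlation 0 of the 31 families passed.

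The 6 arrays can be divided into 3 and 3 in 10 ways. The real division, 1 of these 10, gave 13512 probe sets past the threshold with limma, and the highest of the other divisions gave 0, with 462 to 1292 at an unadjusted p under the same threshold. Every other division mixed the sorts within its groups, which widens their spread, so its count is not a chance level. The 10 divisions are too few for a share under 0.05.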
